A study of Mus musculus with 4 samples.

How the data were processed

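The study profiled N6-methyladenosine (m6A), the most common internal modification of messenger RNA, in cells sorted from mouse cortex. Mice carried APOBEC1-YTH, a fusion of a cytidine deaminase with an m6A-binding domain, and were 10 weeks old when tamoxifen was started. They received 20 mg/kg every 24 hours for 5 days and tissue was taken 7 days later, per the labels. Astrocytes were sorted with an antibody against ACSA2, an epitope of the protein made from Atp1b2, and microglia with an antibody against CD11b, the product of Itgam. GLORI was then applied, per the labels: a chemical treatment deaminates unmethylated adenosine, which is read as G, so that an adenosine still read as A is taken as methylated. Total RNA libraries were made with a stranded low-input kit, per the labels' protocols, although the molecule is entered there as polyadenylated RNA.

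Each of the 4 libraries has 1 deposited table of called sites, with 7 columns and no header: chromosome, start, end, gene name, level, strand and 3-mer. The level is a fraction, deposited by the authors with no coverage, read counts or p-values beside it, and is the share of reads still carrying A at that site. It is given as a percent below. Sites were called with GLORI-tools per the series' design text, and STAR and the build mm39 are named in the submitters' processing notes. The thresholds for calling a site are not given in the sources used here. The lowest listed level was 10.0% in 3 libraries and 10.05% in the other, and every listed site had the 3-mer GAC or AAC. A site absent from a table can be unmethylated, below a calling threshold or unread, and these cannot be separated. The depth of sequencing is unknown, so no value has a counting interval for its level. Positions are the end column of each row, which is the 1-based position of the base in mm39. No sequence or annotation of mm39 was used here, so 5-mer motifs and positions within transcripts were not determined. Gene names are those in the tables. Of 5526 names, 5452 matched a symbol in a RefSeq table of another mouse build, which was used only for gene classes. The authors gave the word ELSE to sites without a gene name, called sites outside named genes below.

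Sites were matched between libraries by chromosome, position and strand. Overlap was measured with the Jaccard index, the shared sites as a percent of all sites in either library. Shares of sites carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting of sites only. Levels were to be tested on read counts at a minimum coverage of 20 reads. The files hold levels only, so the fallback set out for that case was used. This was limma on log2 odds of the level, with levels limited to 0.01 to 0.99, over sites listed in all 4 libraries, without a replicate block. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Sites whose libraries tied within each type, mostly at the upper limit, have no estimate of spread and received no test. This departs from the fit as set out before the data were examined, which kept every site, and the rule was made after the counts of that fit were seen. With tied sites kept, 0 of 1100 sites passed in all 4 libraries, but 909, 1658, 100 and 51 sites passed without astrocyte 1, astrocyte 2, microglia 1 and microglia 2, of which 903, 1654, 100 and 51 were tied. Among 4841 sites listed in at least 1 library of each type 913 passed, 906 of them tied. With the rule, each of these counts was 0. Gene-level tests used the mean log2 odds over a gene's shared sites. In simulated data for this comparison with 354 sites, of which 200 were changed, the test called 65.6% of sites changed by 3 log2 units, 82.7% of those changed by 6 and 6.5% of unchanged sites. The simulated log2 odds were not held to the limits of 0.01 to 0.99, while most shared sites stood at or near the upper limit. These rates therefore do not give the power of the test on these data. With 2 libraries against 2, a two-sided exact permutation test cannot give a p below 0.33.

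A total of 16 gene lists with 394 symbols was fixed before the data were examined: markers of astrocytes, microglia, neurons, oligodendrocytes and their precursors, endothelial and mural cells, and border macrophages with blood myeloid cells, and lists for early response genes, m6A regulators, lipid metabolism, lysosomes, cytokine signalling, Notch, Wnt, Fgf and Bmp signalling, chromatin, ribosomal proteins and synapses. Each list was compared between the types with Fisher's exact test on genes with a site shared by both libraries of 1 type and none shared by both libraries of the other. Genes are not replicates, so these p-values describe the libraries. For differences between 2 single libraries, a list was placed among 10000 random lists matched on its number of listed genes and on the total sites per gene. The percentile describes these 2 libraries and is not a test of the types. That step was added after the data were seen, and in a check on 5526 genes 19 of 20 random lists fell in the central 95% while a planted list reached the percentile 100. No list had the 5 tested sites that the camera gene set test required.

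Genes were to be named by a fixed rule: up to 12 sites per direction past the threshold of the level test, up to 8 genes with the most sites in both libraries of 1 type alone, up to 8 with the most sites in all 4 libraries, up to 4 per list, and both sorting antigens. Ties were broken alphabetically because coverage was not given. The level test named no site, as none passed. Few list genes had a site in both libraries of a type, so the 4 genes per list and the 8 genes per library with the most sites were named as well, a choice made after their values were seen. Some genes that these rules named are not reported here. Analyses used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and limma 3.58.1. Libraries are called by their labels throughout, because the marker genes in both replicate 2 libraries ran against the labels. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these libraries. Planned tests on read counts, coverage minimums and thinning, full 5-mer motifs and transcript regions were left out for want of coverage and of an mm39 sequence. Other settings tried were a level minimum of 50%, matching within 5 nt, leaving out each library, a replicate block, centred levels, sites listed in at least 1 library of each type, and a minimum difference of 10 points.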

Results

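Called m6A sites were compared between astrocytes, the glia that clear neurotransmitter and supply neurons, and microglia, the resident macrophages of the brain, with 2 libraries of each. The library labelled astrocyte 1 listed 12687 sites, astrocyte 2 listed 7231, microglia 1 listed 6343 and microglia 2 listed 8480. Sites in named genes numbered 4790 in 3152 genes for astrocyte 1, 2348 in 1716 genes for astrocyte 2, 1066 in 940 genes for microglia 1 and 3782 in 2609 genes for microglia 2. The remaining sites lay outside named genes. Read depth is unknown for all 4 libraries.

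The first question was whether each library listed sites in the transcripts of the cell type on its label. In astrocyte 1, 27 of 34 astrocyte markers had at least 1 site, against 3 of 35 microglia markers. In microglia 1, 0 of 34 astrocyte markers and 23 of 35 microglia markers had a site. The replicate 2 libraries showed the opposite: the library labelled astrocyte 2 had sites in 1 of 34 astrocyte markers and 27 of 35 microglia markers, and the library labelled microglia 2 had sites in 24 of 34 astrocyte markers and 2 of 35 microglia markers. Of the genes whose products were used for sorting, Atp1b2, a sodium pump subunit, had 1 site in astrocyte 1 at 11.8% and 2 sites in microglia 2, and Itgam had 1 site, in astrocyte 2, at 27.8%. The marker sites of both replicate 2 libraries therefore ran against their labels, and any direction below that rests on those libraries carries this limit.

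**Figure D1:**
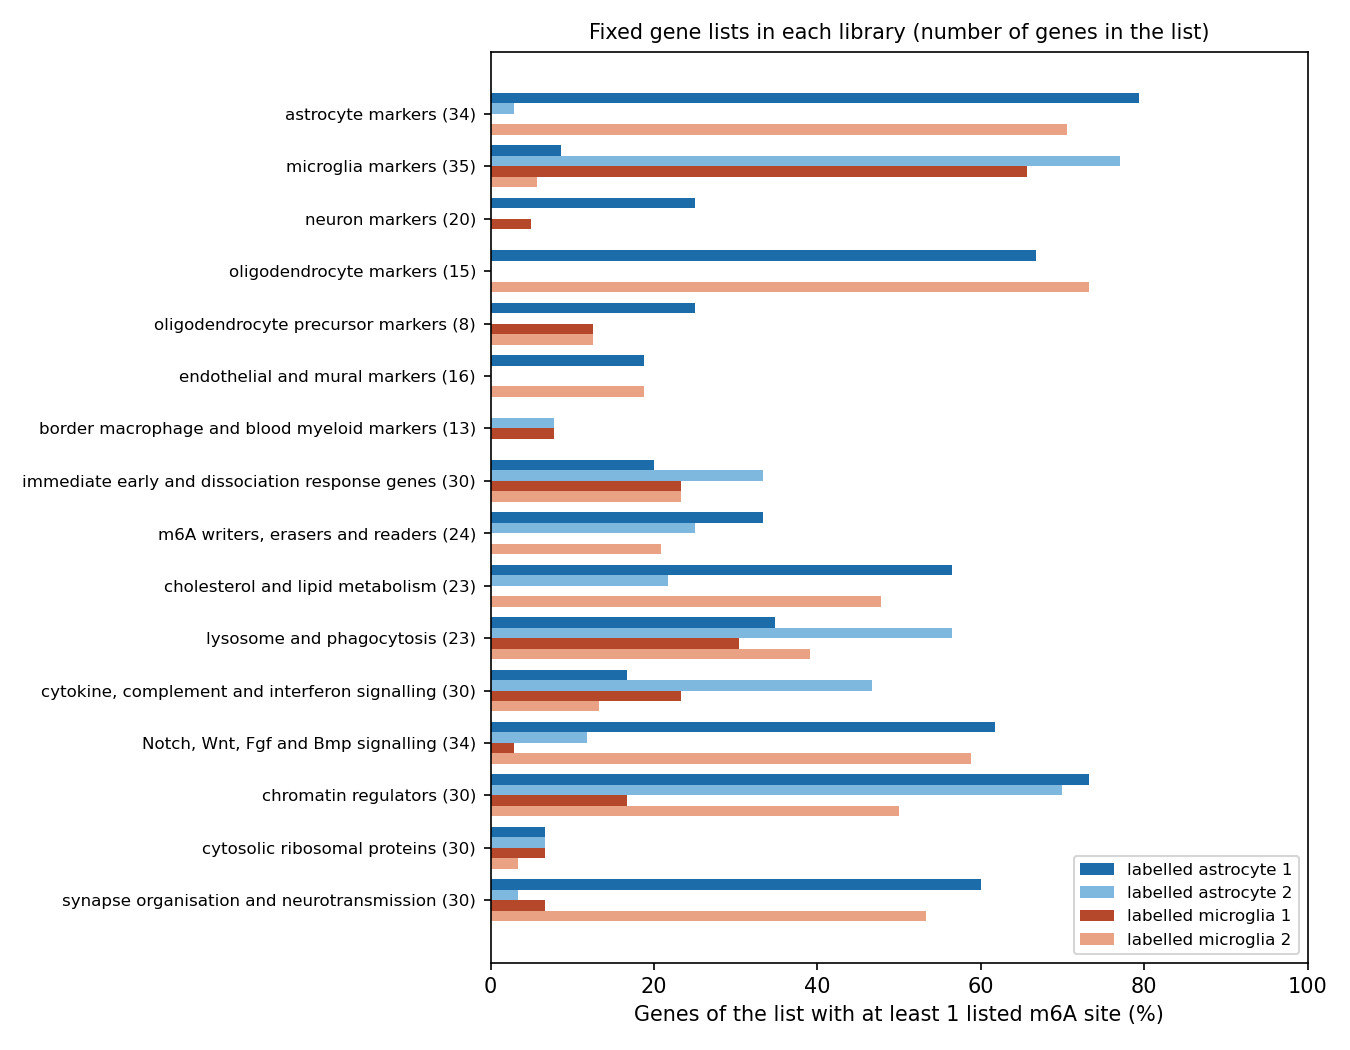
Share of the genes in each fixed list (y axis, with the number of genes in the list) that had at least 1 listed m6A site (x axis, percent), with 1 bar per library, coloured by its label. Astrocyte markers reach 79.4% in astrocyte 1 and 70.6% in microglia 2, and microglia markers reach 65.7% in microglia 1 and 77.1% in astrocyte 2.

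Among astrocyte markers, Slc1a2, the main glutamate transporter of astrocytes, had the most sites, with 14 in astrocyte 1, 13 in microglia 2 and none listed in astrocyte 2 or microglia 1. At 6 of these positions both libraries listed the same base. The level at position 102620681 of chromosome 2 (plus strand) was 50% in both, the level at 102619754 was 24.4% in astrocyte 1 and 27.7% in microglia 2, and the level at 102617962 was 32.6% and 11.8%. Aqp4, the water channel of astrocyte endfeet, had 6 sites in astrocyte 1 and 5 in microglia 2. Slc4a4, a bicarbonate transporter, had 5 in each, and Fgfr3, a growth factor receptor, had 5 and 3. Glul, which encodes glutamine synthetase, was the only astrocyte marker with sites in astrocyte 2, where it had 2. The median level over the 87 astrocyte marker sites of astrocyte 1 was 22.2%, against 66.7% over all its sites in named genes. Over the 62 of microglia 2 it was 20.2%, against 58.9%. Low levels were not particular to these markers: oligodendrocyte markers stood at 28.6% and 30.8% in the same libraries. Genes with 5 or more sites stood at 44.7% and 40.0%. Read depth is unknown, so its part in these medians cannot be separated.

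Among microglia markers, Cx3cr1, the fractalkine receptor, had 7 sites in microglia 1 and 2 in astrocyte 2. P2ry12, a purine receptor of resting microglia, had 6 and 3, Entpd1, an ectonucleotidase, 4 and 3, and Csf1r, the receptor for colony stimulating factor, 4 and 1. None of these 4 genes had a site in astrocyte 1 or microglia 2. Tgfbr1, a receptor for transforming growth factor beta, had 9 sites in astrocyte 2, 2 in microglia 1 and 1 in microglia 2, and the same base at position 47410795 of chromosome 4 (plus strand) was listed at 20.0%, 29.2% and 60.0% in these. In Csf1r the position 61243393 of chromosome 18 was listed at 38.2% in astrocyte 2 and 35.6% in microglia 1. Mertk, a phagocytic receptor also made by astrocytes, had 5 sites in astrocyte 1 and 1 in microglia 2. The median level over microglia marker sites was 43.8% over 48 sites in microglia 1 and 40.0% over 61 sites in astrocyte 2.

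Because the labels of the replicate 2 libraries were in doubt, the types were also compared in the replicate 1 libraries alone, which gives no replicate check and no test. Astrocyte 1 listed 9451 sites that microglia 1 did not, 4457 of them in named genes. Microglia 1 listed 3107 that astrocyte 1 did not, 733 in named genes, and 3236 were shared. Astrocyte 1 had sites in 21 of 34 genes of Notch, Wnt, Fgf and Bmp signalling and microglia 1 in 1, a difference at the percentile 98.73 of matched random lists. Examples were Notch2 with 6 sites, Ptch1, the hedgehog receptor, with 6, and Fgfr2 with 4 in astrocyte 1, and none of these had a site in microglia 1. In cholesterol and lipid metabolism 13 of 23 genes had sites in astrocyte 1 and 0 in microglia 1, at the percentile 99.01. They included Scd2, a fatty acid desaturase, with 9 sites at a median level of 12.7%, Abca1, a cholesterol exporter, with 4, and Srebf2, a regulator of cholesterol synthesis, with 4. In the synapse list 18 of 30 genes had sites in astrocyte 1 and 2 in microglia 1, at the percentile 97.3, inside the central 95% of random lists. Kcnj10, the potassium channel of astrocytes, had 7 sites and Gria2, a glutamate receptor subunit, had 7 in astrocyte 1. Markers of other cell types moved with these 3 lists in the same libraries: neuron markers had sites in 5 genes of astrocyte 1 and 1 of microglia 1 (percentile 94.78), and oligodendrocyte markers in 10 and 0 (percentile 94.08).

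Immune lists stood lower among the random lists. In cytokine, complement and interferon signalling 5 of 30 genes had sites in astrocyte 1 and 7 in microglia 1, where the median of the matched random lists was 9 more in astrocyte 1, and the list stood at the percentile 0.02. Il10ra, the receptor for interleukin-10, had 5 sites in microglia 1 and Tgfb1 had 3, and neither had a site in astrocyte 1. In the lysosome and phagocytosis list 8 of 23 genes had sites in astrocyte 1 and 7 in microglia 1, at the percentile 0.4, with 3 sites in Ctsd, a lysosomal protease, in microglia 1 and none in astrocyte 1. Immediate early and dissociation response genes had sites in 6 of 30 genes of astrocyte 1 and 7 of microglia 1, at the percentile 0.14. Chromatin regulators stood at the percentile 85.67, with sites in 22 of 30 genes of astrocyte 1 and 5 of microglia 1. Kmt2d, a histone methyltransferase, had 11 sites in astrocyte 1, 8 in astrocyte 2, 2 in microglia 1 and 9 in microglia 2. The regulators of m6A itself had sites in 8 of 24 genes of astrocyte 1 and 0 of microglia 1, at the percentile 85.85, among them Alkbh5, an m6A demethylase, with 2 sites. Cytosolic ribosomal protein genes had sites in 2 of 30 genes in each of these libraries, at the percentile 12.3.

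The replicate 2 libraries went the other way in some of these lists and not in others. Notch, Wnt, Fgf and Bmp signalling genes had sites in 4 of 34 genes of astrocyte 2 and 20 of microglia 2 (percentile 0.36), and synapse genes in 1 and 16 of 30 (percentile 0.12). Cytokine genes had sites in 14 of 30 genes of astrocyte 2 and 4 of microglia 2 (percentile 100), and immediate early genes in 10 and 7 of 30 (percentile 98.26). Lysosome genes had sites in 13 and 9 of 23 (percentile 99.48), more in the library labelled astrocyte as in replicate 1, but at the other end of the random lists. Cholesterol genes had sites in 5 and 11 of 23 genes (percentile 20). Other lists had more genes with a site in the library labelled astrocyte in both replicates. Chromatin regulators had sites in 21 of 30 genes of astrocyte 2 and 15 of microglia 2 (percentile 99.96) and m6A regulators in 6 and 5 of 24 (percentile 90.49). Single genes also departed from their list: Notch2 had 9 sites in astrocyte 2 and 4 in microglia 2, and Abca1 had 4 and 2.

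Markers of other cell types were also listed. Oligodendrocyte markers had sites in 10 of 15 genes of astrocyte 1 and 11 of 15 of microglia 2, the libraries with most astrocyte marker sites, and in 0 of 15 of astrocyte 2 and of microglia 1. Mbp, a myelin protein, had 1 site in astrocyte 1 and 4 in microglia 2, and Cnp had 3 and 4. Neuron markers had sites in 5 of 20 genes of astrocyte 1, 1 of microglia 1 and 0 of the replicate 2 libraries. Oligodendrocyte precursor markers had sites in 2 of 8 genes of astrocyte 1, 1 of microglia 1, 1 of microglia 2 and 0 of astrocyte 2. Endothelial and mural markers had sites in 3 of 16 genes of astrocyte 1 and of microglia 2 and 0 of the others. Of the border macrophage and blood myeloid markers, Stab1 had 3 sites in astrocyte 2 and 1 in microglia 1, and no other of the 13 genes had a site in any library.

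Compared as labelled, with 2 libraries of each type, 252 sites were listed in both astrocyte libraries and neither microglia library, 69 of them in named genes, and 285 were listed in both microglia libraries and neither astrocyte library, 42 in named genes. A further 1100 sites were listed in all 4 libraries, 83 in named genes. The genes in the first set each had 1 such site, among them Actb, Akap8l, Arf6, Atl3 and Atn1. In the second set Col23a1, a collagen, and Nemf, a factor of ribosome quality control, had 2 each. Both counts hung on single libraries. Sites in astrocytes alone numbered 5150 without astrocyte 1, 8322 without astrocyte 2, 432 without microglia 1 and 577 without microglia 2, and sites in microglia alone 1258, 375, 4986 and 2833. In the replicate 1 libraries alone the counts were 9451 and 3107, and in the replicate 2 libraries alone 5514 for astrocyte 2 and 6763 for microglia 2. Genes with at least 1 site shared by both astrocyte libraries and none shared by both microglia libraries numbered 148, and 139 showed the reverse; such a gene can still have other sites in the other type, as Kmt2d did. Of the 16 lists, 6 had such a gene, with 3 chromatin regulators (Chd4, Kdm6b and Kmt2d) in astrocytes and 3 lysosome genes in microglia as the highest counts. By Fisher's exact test 0 of 6 lists passed the threshold, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.726. Each list held so few such genes that no split of them between the types could give an unadjusted p under 0.05. The test could therefore call no list, and its outcome says nothing on whether the lists differ.

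Overlap of all sites did not follow the labels in one direction. The Jaccard index was 10.28% for the astrocyte pair, below all 4 pairs with different labels, and 19.78% for the microglia pair, above 3 of them. Those pairs stood at 20.49% for astrocyte 1 with microglia 1, 17.82% for astrocyte 1 with microglia 2, 12.93% for astrocyte 2 with microglia 1 and 12.27% for astrocyte 2 with microglia 2. The mean was 15.03% for the same label and 15.88% for different labels, and the order turned to 19.78% and 12.6% without astrocyte 1 and to 19.78% and 19.16% without astrocyte 2. Over all sites in named genes astrocyte 1 with microglia 2 stood at 7.77%, astrocyte 1 with microglia 1 at 6.03%, astrocyte 2 with microglia 1 at 5.14% and the microglia pair at 5.0%. At a level of 100% the highest values were 11.22% for astrocyte 1 with microglia 1 and 11.01% for the microglia pair. For sites in named genes with a level below 100%, a subset chosen after the data were seen, the highest values were 5.83% for astrocyte 1 with microglia 2 and 3.69% for astrocyte 2 with microglia 1. The astrocyte pair reached 1.71% and the microglia pair 1.65%. The index cannot exceed the size of the smaller library relative to the larger one. As a percent of the smaller library, shared sites were 15.8% for astrocyte 2 with microglia 1 and 13.9% for the microglia pair. This share was 13.7% for astrocyte 1 with microglia 1 and 11.5% for astrocyte 1 with microglia 2. It was 7.6% for astrocyte 2 with microglia 2 and 5.7% for the astrocyte pair. Over genes with a site, astrocyte 1 and microglia 2 shared 1386 genes, a Jaccard index of 31.68%. The other 5 pairs lay between 10.08% and 16.46%, where astrocyte 2 with microglia 1 stood at 13.94%. The gap was smaller as a percent of the smaller library. There astrocyte 1 with microglia 2 stood at 53.1%, astrocyte 1 with microglia 1 at 47.1% and the astrocyte pair at 40.1%. The remaining pairs each stood at 34.6%. A two-sided exact permutation test of 2 libraries against 2 cannot give a p below 0.33.

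**Figure D2:**
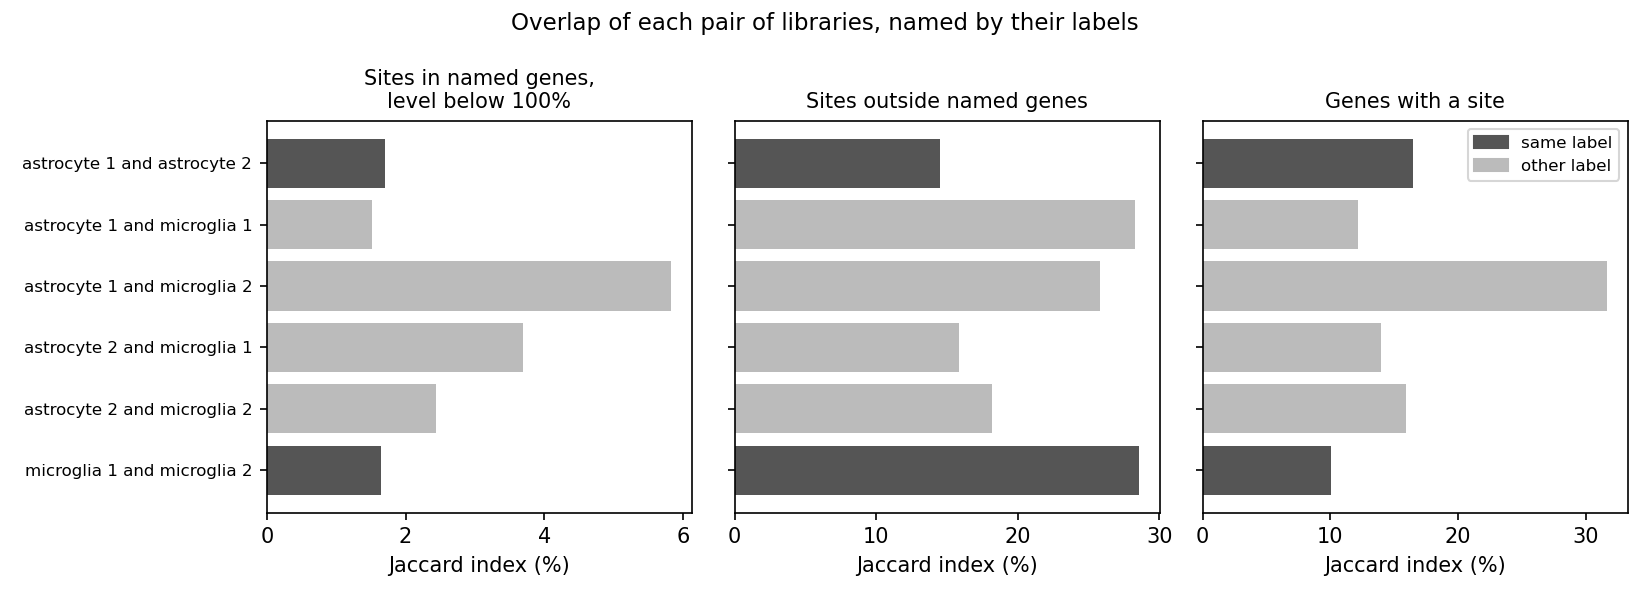
Jaccard index in percent (x axis, a separate scale for each panel from 0) for each of the 6 pairs of libraries (y axis), for sites in named genes with a level below 100%, for sites outside named genes and for genes with a site. Dark bars are pairs with the same label. The longest bars in the first and last panels, 5.83% and 31.68%, belong to astrocyte 1 with microglia 2. The index is limited by how far the 2 libraries differ in size.

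The next question was whether the level at a given site differed between the types. Over the 1100 sites listed in all 4 libraries the median level was 100% in each, and the mean was 96.79% and 97.25% in the astrocyte libraries and 97.04% and 96.57% in the microglia libraries, a difference of 0.21 points (exact two-sided permutation p = 0.667). All 4 libraries stood at 100% at 709 of these sites, and 1017 of them lay outside named genes. Over the 83 in named genes, a subset chosen after the data were seen, the astrocyte minus microglia difference in mean was -0.3 points. Of 354 sites that could be tested, limma called 0 at an adjusted p under 0.05, with 16 at an unadjusted p under 0.05 and a smallest adjusted p of 0.457. With the fit limited to sites in named genes, limma called 0 of 48 tested. Of 47 genes tested, 0 passed and 2 had an unadjusted p under 0.05. The named gene with the lowest p was Pkd1, named after its values were seen, whose site at position 24814738 of chromosome 17 had a mean of 69.4% in the libraries labelled astrocyte and 100% in those labelled microglia (limma, adjusted p = 0.457). A total of 746 sites tied within the types and had no test. Such sites have no estimate of spread, so a call there does not show a difference in level. With tied sites kept, limma called 0 of 1100, but 909 without astrocyte 1, 1658 without astrocyte 2, 100 without microglia 1 and 51 without microglia 2, against 0 in each case without them. With labels in doubt this test cannot speak to the cell types.

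Between any 2 libraries, levels at shared named-gene sites below 100% in both correlated across sites, which are not independent replicates. Pearson's r was 0.76 over 83 sites for the astrocyte pair and 0.86 over 59 sites for the microglia pair, the highest of the 6. For pairs with different labels it was 0.80 over 58 sites for the replicate 1 libraries, 0.68 over 111 sites for the replicate 2 libraries, 0.65 over 368 sites for astrocyte 1 with microglia 2 and 0.80 over 67 sites for astrocyte 2 with microglia 1. The SD of the difference between 2 libraries at such sites was 15.3 to 20.8 points over the 6 pairs, pooled over sites. Malat1, a nuclear long non-coding RNA, had 2 sites listed in all 4 libraries, the most of any gene. The level at position 5848296 of chromosome 19 (minus strand) was 17.5% ± 2.3 (SD, n = 4 libraries), and at 5846790 it was 20.3% ± 8.4 (SD, n = 4). The site in Bdnf, a neurotrophin gene, at position 109553975 of chromosome 2 stood at 93.1% ± 2.3 (SD, n = 4). Rpl7a, a ribosomal protein gene, had a site at position 26802856 of chromosome 2 at 98.9% ± 2.2 (SD, n = 4), and Arsb, a lysosomal sulfatase, had one at position 94079284 of chromosome 13 at 93.0% ± 11 (SD, n = 4).

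Sites in named genes and outside them differed in sequence and level. The 3-mer GAC made up 67.6% of named-gene sites in astrocyte 1 (95% interval 66.27 to 68.94), 65.0% in astrocyte 2 (63.07 to 66.96), 56.8% in microglia 1 (53.81 to 59.85) and 69.4% in microglia 2 (67.86 to 70.82). Outside named genes it made up 44.1%, 43.5%, 39.1% and 42.5%, and AAC was the more frequent 3-mer. Sites outside named genes were 62.24% of all sites in astrocyte 1, 67.53% in astrocyte 2, 83.19% in microglia 1 and 55.4% in microglia 2. Their level was 100% at 73.0% to 89.4% of sites over the 4 libraries, against 15.3% to 60.3% of sites in named genes. The median level of named-gene sites was 66.7% in astrocyte 1, 80% in astrocyte 2, 100% in microglia 1 and 58.9% in microglia 2. It was equal for GAC and AAC in 3 libraries, to 1 decimal, and stood at 58.6% for GAC and 60% for AAC in microglia 2.

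**Figure D3:**
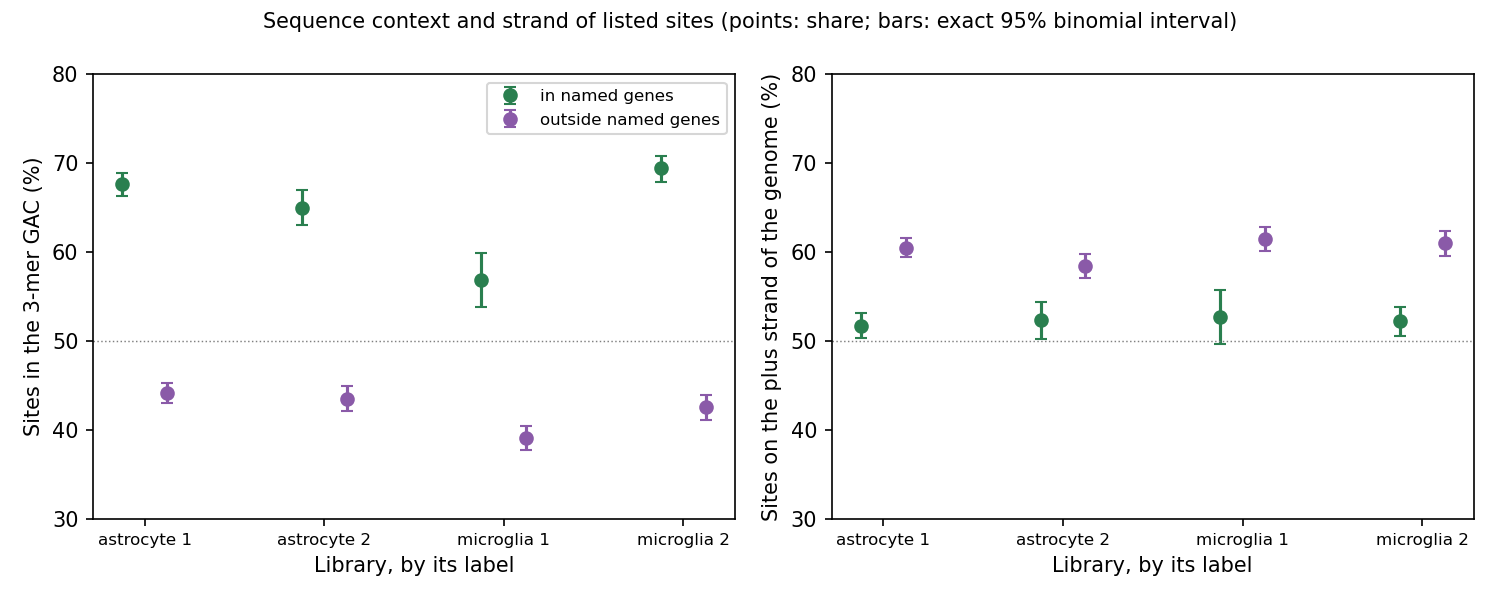
Share of sites in the 3-mer GAC (left, percent) and on the plus strand of the genome (right, percent) for each library (x axis), in named genes and outside them, with points for the share, bars for exact 95% binomial intervals and a dotted line at 50%. GAC falls from 56.8% to 69.4% in named genes to 39.1% to 44.1% outside, and the plus-strand share goes from 51.7% to 52.7% in named genes to 58.4% to 61.5% outside.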

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

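All tests in this part were chosen after the results were seen. In the astrocyte and microglia marker lists the contrast between the types ran in opposite directions in the replicate 1 and the replicate 2 libraries, and this difference between replicate numbers was not tested. For astrocyte markers, astrocyte 1 had sites in 27 more genes than microglia 1, while the library labelled astrocyte 2 minus the library labelled microglia 2 gave -23. For microglia markers the same differences were -20 and 25. Among matched random lists these stood at the percentiles 100 and 0.0 for astrocyte markers and 0.0 and 100 for microglia markers.

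A mixture of both cell types in each replicate 2 library is argued against, because only 1 of 34 astrocyte markers had a site in astrocyte 2 and only 2 of 35 microglia markers in microglia 2. A shortage of listed sites is argued against as well, since astrocyte 2 had sites in 27 microglia markers and 2348 sites in named genes, more than microglia 1. An exchange of the labels of the replicate 2 libraries, at any step from sorting to deposit, has the partner out of place that it needs in each type and may account for the markers, but sites outside the marker genes did not decide it. There, for named-gene sites below 100%, the Jaccard index was 5.63% for astrocyte 1 with microglia 2 and 3.38% for astrocyte 2 with microglia 1, against at most 2.5% for the other 4 pairs, while the sites shared as a percent of the smaller library were 11.1% and 15.3%, against 15.3% for astrocyte 1 with microglia 1 and for the microglia pair. Levels at shared sites correlated best in the microglia pair in named genes (r 0.86) and in astrocyte 1 with microglia 2 outside them (r 0.88), and no biological explanation was tested.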

How the results depend on the processing

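Of 24 results recomputed under 128 alternative values, 66 stayed on the same side or within their spread, 58 moved and 4 changed sign. Settings with named or outside sites only, levels below 100%, a level minimum for the share in named genes, single replicate numbers, tied sites, the crossed block and overlap without each library were chosen after the data were seen. The count of sites with different levels stayed at 0 with the replicate block (0 of 354) and, as long as tied sites had no test, in every setting but the crossed block, which paired each replicate 1 library with the replicate 2 library of the other type and called 1 of 353. Levels less their label's mean correlated between same-numbered libraries at -0.097 (all sites) and -0.146 (83 named-gene sites), and listing at 0.088 (10598 such sites). With labels in doubt these cannot show pairs, and none were assumed. With tied sites kept, as the fit was first set out, the count stayed at 0 in all 4 libraries with and without the block, but rose to 909 without astrocyte 1, 1658 without astrocyte 2, 100 without microglia 1, 51 without microglia 2 and 913 among sites listed in at least 1 library of each type, and for genes to 53, 101, 15 and 4 without each library. Nearly all of these site calls and all of the gene calls were tied. Log2 odds were not rounded in that fit. A tied site has no estimate of spread, so a call there does not show a difference in level. Over sites listed in all 4 libraries the count was 0 with and without tied sites. In other fits the 0 rests on leaving out tied sites, a rule made after these counts were seen. The count of genes otherwise stayed at 0, and so did that of lists. Leaving out 1 library leaves a type with 1 library whose spread is assumed to match the other type's. With all medians at the upper limit, centring moved no level and tests nothing. With a library left out, fewer libraries have to list a site or to lack it. Sites listed in 1 type alone then ranged from 432 (without microglia 1) to 8322 (without astrocyte 2) for astrocytes. For microglia these sites ranged from 375 (without astrocyte 2) to 4986 (without microglia 1). Without both replicate 2 libraries they numbered 9451 and 3107, without both replicate 1 libraries 5514 and 6763, below a level of 100% 64 and 50, and below 100% without both replicate 2 libraries 5360 and 731. Within genes with a site shared by all libraries used of each type, 2 astrocyte and 1 microglia sites became 1 and 0 at levels of at least 50%, 1 and 1 below 100%, 334 and 158 without both replicate 2 libraries, 595 and 649 without both replicate 1 libraries, and 142 and 79 below 100% without both replicate 2 libraries. Without each library in turn they ranged from 13 to 85 and from 15 to 87. Astrocyte markers with a site shared by the astrocyte libraries only minus those by the microglia libraries only, 1 as labelled, ranged from -23 (without microglia 1) to 27 (without astrocyte 2). Microglia markers, -1 as labelled, ranged from -23 (without microglia 2) to 26 (without astrocyte 1), with 2 without astrocyte 2 and 4 where 1 library of a type sufficed. The mean Jaccard index of 15.03% for the same label and 15.88% for different labels became 4.22% and 5.76% in named genes and 1.68% and 3.37% in named genes below 100%, and 22.02% for different labels outside named genes. It ranged from 10.28% to 19.78% and from 12.6% to 19.16% without each library, and its order turned without astrocyte 1 (19.78% and 12.6%) and without astrocyte 2 (19.78% and 19.16%). At levels of at least 50%, named genes held 30.65%, 26.97%, 14.86% and 34.93% of sites in astrocyte 1, astrocyte 2, microglia 1 and microglia 2, and GAC made up 51.4% in astrocyte 1, 49.3% in astrocyte 2 and 51.7% in microglia 2. The cause of these shifts was not tested. Coverage minimums, thinning, edgeR and Fisher tests on reads, pooled levels, full 5-mer motifs, positions in transcripts and camera were not run, for want of coverage, sequence or tested list sites. Unknown depth limits every statement that a site is absent.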

Other observations

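The genes with the most sites were in part shared between libraries and in part different. Slc1a2 led in astrocyte 1, with 14 sites, and in microglia 2, with 13. Kmt2d was among the 8 genes with the most sites in astrocyte 1 (11), astrocyte 2 (8) and microglia 2 (9). Malat1 was among them in astrocyte 2 (9) and microglia 1 (5). After Slc1a2, astrocyte 1 listed 13 sites each in Appl2, an endosomal adaptor, and Pcdh9, a protocadherin, 11 in Ptprz1, a receptor phosphatase, 10 in Farp1, 11 in Xist and 10 in Neat1, and the last 2 are long non-coding RNAs. Microglia 2 listed 11 sites in Ddx17, an RNA helicase, and 9 each in Pcdh9, Fat1, Arhgef12 and Pkd1. Astrocyte 2 listed 10 in Ssh2, a cofilin phosphatase, 9 in Notch2, 8 in Zfhx3 and 7 in Lrp1, and microglia 1 listed 6 in Mpeg1, a macrophage perforin. Xist had 5 sites in microglia 2 and none listed in astrocyte 2 or microglia 1.

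Of the 83 named-gene sites in all 4 libraries, 34 stood at 100% in each and 9 stood below 50% in each. Among those 9 were small nucleolar RNAs, which guide the modification of other RNAs: Snord2 at 18.4% ± 4.0, Snord21 at 21.4% ± 3.4 and Snord38a at 22.0% ± 3.1 (SD, n = 4). Small non-coding RNAs made up 4 of these 9 sites and 4 of the other 74, with 5 and 70 sites in other genes. The two-sided p was 0.0039 by Fisher's exact test across sites, chosen after the values were seen. The median level in small non-coding RNAs was 18.2% to 21.1% over the 4 libraries. Sites in genes with more sites had lower levels: in astrocyte 1 the median was 80% in genes with 1 site and 44.7% in genes with 5 or more, and in microglia 2 it was 60% and 40%.

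The tests in the next paragraphs were chosen after the results were seen, and the prediction for each chromosome was set before its values were computed. Sites outside named genes lay on the plus strand of the genome more often than sites in named genes, in all 4 libraries. The plus-strand share would match that of named genes if methylated sites of transcripts without a gene name were their whole source. This assumes that such transcripts divide between the strands as named genes do, which was not tested. The 2 intervals were instead at least 2.69 points apart in every library. A placement of reads that depends on the genome strand should act on every chromosome. The lower bound was above 50% on 19 of 20 chromosomes, with shares of 53.7% to 66.1% over distinct sites. These values argue against an excess carried by a few chromosomes. Any other excess spread over the genome would give the same result, so they do not single out read placement. Part of these sites may still be methylated, and no biological explanation from the design was tested.

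The overlap of sites outside named genes did not follow the marker genes: the Jaccard index was 28.58% for the microglia pair, 28.26% for astrocyte 1 with microglia 1, 25.81% for astrocyte 1 with microglia 2, 18.2% for astrocyte 2 with microglia 2, 15.81% for astrocyte 2 with microglia 1 and 14.51% for the astrocyte pair.

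Oligodendrocyte markers had sites in 10 of 15 genes of astrocyte 1, 11 of 15 of microglia 2 and 0 of the other libraries, and the abundant Mbp had 1 site in astrocyte 1 and 4 in microglia 2. RNA of all brain cells alike would also bring microglia RNA. Microglia markers had sites in 3 of 35 genes of astrocyte 1 and 2 of microglia 2, against 23 in microglia 1 and 27 in astrocyte 2. These counts were low in astrocyte 1 and microglia 2, but a marker without a listed site can be unread at the unknown depth. They therefore do not decide that source. Neuron markers do not decide it either. All 5 with a site in any library had one in astrocyte 1 and 0 had one in microglia 2. Among matched random lists they stood at the percentile 94.78 in replicate 1, against 94.08 for oligodendrocyte markers. In replicate 2, where no neuron marker had a site in either library, they stood at 61.76, against 0.02. Oligodendrocyte RNA carried with the sorted cells stays open as a candidate source. Its list lay outside the central 95% of random lists, at 0.02, in replicate 2 and inside it, at 94.08, in replicate 1. The ACSA2 gate should remove oligodendrocytes from astrocyte 1, and the CD11b gate named on the label of microglia 2 should do so as well. The marker sites of microglia 2 ran against that label. Of the 15 genes 0 are in another list, though how many astrocytes also express was not tested.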
